A study of Saccharomyces cerevisiae S288C with 6 samples.

How the data were processed

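RNA from 6 cultures of S. cerevisiae S288C, 3 treated with plakortide F acid (PFA) at 0.62 ug/ml and 3 with 0.25% DMSO, was labelled with biotin and hybridized to 1 Affymetrix Yeast Genome 2.0 array each. Groups and replicate numbers were taken from the sample titles, which call the samples biological replicates, and p-values measure the spread among them. The deposited values are signal intensities on a linear scale, 1 per probe set. Per the submitters' processing notes, the software was GCOS 1.1. The summary algorithm and background step are not given in the sources used here. In the deposited intensity values, the mean without the lowest and highest 2% of probe sets was 1001 on each array, so the arrays had been scaled to a common level by the authors, and no scaling was added here. Such scaling sets changes relative to the average of the array, so a shift of all transcripts in a group would not be seen.

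The table held 10928 probe sets. Through the platform annotation and the RefSeq gene table, 5498 matched a single S. cerevisiae gene, with 12 symbols updated, and these covered 5449 genes. A further 1746 carried the name of another organism (the array also holds Schizosaccharomyces pombe probe sets), 1 carried several genes, 3517 were unnamed in the annotation used and 166 were controls. No genome coordinates were used. The background level was the 95th percentile of the mean log2 signals of the other organism's probe sets, a signal of 20.01 (log2 4.32). Genes whose mean log2 signal was above it were tested, which left 93 out, and the probe set with the highest mean stood for a gene. Of 42 genes with several tested probe sets, 1, PAU23, had probe sets called in opposite directions. Probe sets shared between sequences stood for 113 genes, whose values can mix near-identical copies.

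All deposited intensities were above 0, so log2 was taken without a pseudocount. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided, Benjamini-Hochberg over all genes tested, threshold 0.05), without a replicate block. Fold changes are ratios of geometric means, and means ± SD are of the linear signals. Where the mean log2 signal of a group was below background, the fold is a lower bound, the mean log2 signal of the brighter group against the background level. For PRM6, PRM2, AGA2 and SFC1, where not all 3 arrays were below, this was chosen after their values were seen. Shifts of 37 gene lists were tested with camera at a preset correlation of 0.01 for the 36 lists with at least 5 members, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in a direction without comparing them with other genes, were alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

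The grouping, the tests, the lists, the alternatives and the rule for naming genes were set before the data were examined. The rule named the 12 largest rises and 12 largest falls among genes with a standard symbol, an adjusted p under 0.05 and groups that did not overlap. It also named up to 4 changed members with the largest change from each list with at least 2 such members, and PMC1, PMR1, RCN1, CMK2, CRZ1, CNB1, ENA1, PDR5, ERG11, HSP12, PHO84 and ACT1 whatever their result. GDT1, MID1, YVC1, PHO89, PRM4, STE6, BAR1, RPP1, GSY1, GSY2, GPH1, GLG1, PGM2 and SOL4 were named after their values were seen. Among list members, ENA1, ENA2, PHO12, TDH2, HXT6, HXT16 and HHF2 had no probe set under that name in the annotation used, some others are not reported here, and AZR1, HXT10, HXT11, HXT13, HXT15, MLS1, SPS2 and DIT2 did not pass the filter.

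The procedure was tested on simulated data for the PFA against DMSO comparison, made from the means and spreads of the 5356 genes with 200 genes changed at random and the 33 proteasome genes shifted, 231 genes in all. Of the 198 outside the shifted list it recovered 83.3% (55 of 66) of log2 changes of 0.585, 94.0% (63 of 67) of log2 changes of 1 and 98.5% (64 of 65) of log2 changes of 2, and called 10 of 5125 unchanged genes. The shifted list was called and 0 of the others. The noise was drawn independently for each gene and far fewer genes changed than in the data. The list result therefore does not bear on lists whose genes vary together. Alternatives were a replicate block, quantile normalization, centring on the median, no filter, a stricter filter, pseudocounts of 16 and 64, eBayes without trend, leaving out each array, all probe sets and, added after the data were seen, probe sets specific to a gene alone and the ribosomal protein list without RPP1.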

Results

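Transcript levels were measured in Saccharomyces cerevisiae S288C, the haploid alpha-mating-type reference strain of budding yeast, after exposure to plakortide F acid (PFA), an antifungal endoperoxide polyketide of marine sponges. Cultures in buffered synthetic glucose medium received PFA at its IC50, 0.62 ug/ml, when they had reached an optical density of 0.2, and were collected at 0.5. Control cultures received 0.25% DMSO, the solvent. The time each culture took, and whether the PFA cultures held the same amount of DMSO, are not given in the sources used here, so a part of the solvent in the changes cannot be judged. Each group held 3 biological replicates, 1 Affymetrix Yeast Genome 2.0 array each, and these 6 arrays limit the precision. The authors' scaled signal intensities had a trimmed mean of 1001 on each array, and 98.1% to 98.7% of the S. cerevisiae probe sets on an array lay above the background level of 20.01. Ratios of 3' to 5' signal for ACT1, a measure of RNA quality, were 1.20 to 1.28 in DMSO and 1.19 to 1.25 in PFA. Those for SPT15 were 2.13 to 2.40 in DMSO and 2.13 to 2.29 in PFA, and those for WBP1 1.86 to 2.70 in DMSO, the highest in DMSO replicate 1, and 2.25 to 2.34 in PFA.

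The comparison of PFA with DMSO addressed which genes respond to the compound at a growth-inhibiting dose. By camera with a preset correlation, lists of calcium signalling, glucose-repressed metabolism, nitrogen scavenging and general stress genes shifted up in PFA and lists of mating, cell division and ribosome genes shifted down, not every member with them. With a correlation estimated within each list, 0 of 36 lists passed an adjusted p under 0.05. Of 5356 genes tested, 3323 (62.0%) changed at a limma adjusted p under 0.05, with 1622 higher and 1701 lower in PFA. A change of at least 1.5-fold was found for 1271 genes, 715 higher and 556 lower, and a change of at least 4-fold for 82 higher and 32 lower. The balance depended on scaling: centring each array on its median gave 1416 higher and 1982 lower, and at 1.5-fold 613 and 713, and quantile normalization gave 1501 higher and 1803 lower, and at 1.5-fold 633 and 646. The median log2 change of all genes was -0.02. In 3565 genes (66.6%) the 3 PFA values did not overlap the 3 DMSO values, where chance gives 10% of genes. Correlations between arrays were 0.991 to 0.994 within a group and 0.923 to 0.929 between groups, and the first principal component, which separated the groups, held 87.3% of the variance. Requiring a signal above the median of the yeast probe sets left 2724 genes, of which 1893 changed.

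**Figure D1:**
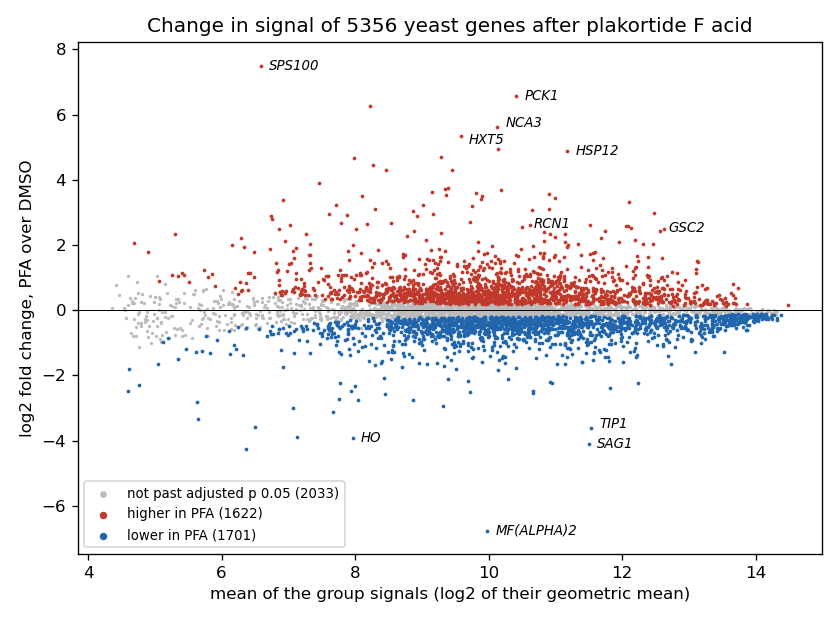
Log2 fold change (PFA over DMSO) of each of the 5356 genes against the log2 of the geometric mean of its group signals, with red and blue points for the 1622 genes higher and the 1701 lower at an adjusted p under 0.05 and grey points for the rest. Fitted changes reach 7.50 for SPS100, whose DMSO signal was below background, and -6.77 for MF(ALPHA)2, while most genes lie near 0.

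Among the largest rises, PCK1 (YKR097W), which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, went from a signal of 142 ± 25.9 in DMSO to 13194 ± 612 in PFA (SD, n = 3), a 94.2-fold increase (limma adjusted p = 7.19e-13). NCA3 rose 49.7-fold, the hexose transporter gene HXT5 40.8-fold, the stationary-phase gene SPG4 30.8-fold and HSP12, encoding a small membrane-associated stress protein, 29.4-fold. PUT1, encoding proline oxidase, rose 26.1-fold, the peptide transporter gene PTR2 25.5-fold and the branched-chain amino acid permease gene BAP2 22.1-fold. BAG7 rose 19.9-fold, RTA1 19.8-fold and XBP1, encoding a stress-induced repressor, 15.1-fold. SPS100, a spore wall gene, was below background on all 3 DMSO arrays and at 1208 ± 116 in PFA (SD, n = 3), at least 60.2-fold higher. That bound sets the PFA mean against the background level. Of the genes that fell, MF(ALPHA)2 (YGL089C), which encodes alpha-factor pheromone, went from 10528 ± 122 to 97 ± 12.5 (SD, n = 3), or 109-fold lower (adjusted p = 1.3e-13). HO, the mating-type switching endonuclease gene, was 15.1-fold lower, the cell wall sensor-like gene WSC4 14.9-fold lower and the cell wall mannoprotein gene TIP1 12.2-fold lower. The remaining 8 of the 12 largest falls, among them SAG1 and FAR1, belong to the mating genes and cell-type markers described further on.

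All 14 measured calcineurin-Crz1 targets, genes activated through the calcium-dependent phosphatase calcineurin and its transcription factor Crz1, rose in PFA, with a median log2 change of 1.59. The glucan synthase gene GSC2 rose 5.34-fold, the calcineurin regulator gene RCN1 5.26-fold, from 794 ± 83 to 4156 ± 69.6 (SD, n = 3), and the cell-surface protease gene YPS1 4.44-fold. PMC1, encoding the vacuolar calcium pump, rose 3.33-fold, from 1611 ± 48.8 to 5361 ± 166 (SD, n = 3), the calmodulin-dependent kinase gene CMK2 3.01-fold, CRZ1 itself 1.98-fold and the Golgi calcium pump gene PMR1 1.49-fold. The sodium pump gene ENA5 rose 4.1-fold, but near-identical ENA copies share its sequence, so the copy is uncertain, and ENA1 had no probe set under that name in the annotation used. Adjusted over the list alone, 14 of the 14 rose as well, and camera gave an adjusted p of 1.47e-09 (adjusted p = 0.171 with an estimated correlation).

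**Figure D2:**
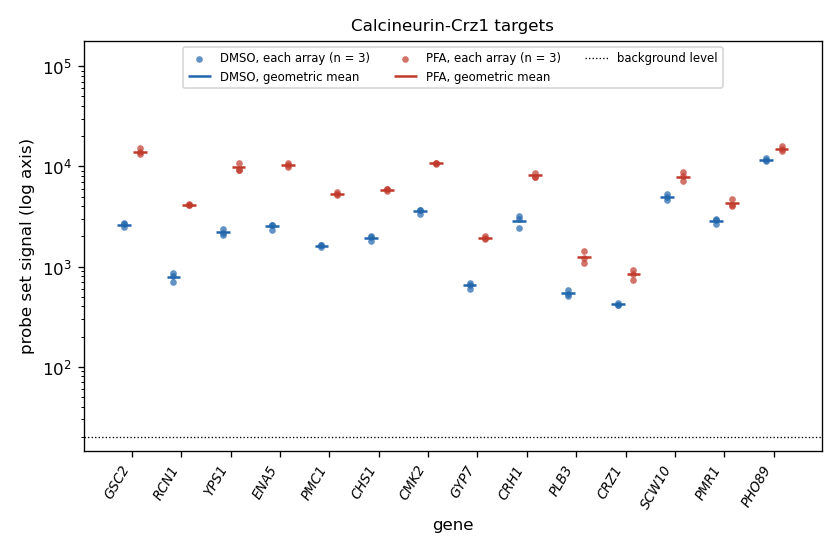
Probe set signal (log axis) of the 14 calcineurin-Crz1 targets on each of the 3 DMSO (blue) and 3 PFA (red) arrays, with bars for the geometric means and a dotted line at the background level of 20.01. All 14 lie higher in PFA, from GSC2 at 5.34-fold on the left to PHO89 at 1.28-fold on the right.

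Of the 18 genes of calcium transport and signalling, 11 rose, 3 fell and 4 did not pass the test, and 5 of them are also Crz1 targets. RCN2, a second calcineurin regulator gene, rose 4.09-fold. The log2 changes of the 3 that fell were -1.19 for GDT1, a Golgi calcium transport gene, -0.44 for MID1, part of the plasma membrane calcium channel, and -0.35 for the vacuolar channel gene YVC1. CNB1, the regulatory subunit of calcineurin, had a log2 change of -0.13 ± 0.07 (SE, adjusted p = 0.146). The list shifted up (camera adjusted p = 0.00407, adjusted p = 0.189 with an estimated correlation), and 12 rose and 3 fell adjusted over the list alone. The 5 shared genes, PMC1, PMR1, RCN1, CMK2 and CRZ1, all rose. A shift of the list without them was not tested, so it is not a result separate from the Crz1 targets.

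In the list of general stress and reserve carbohydrate genes 20 of 32 rose and 6 fell. Those that fell were GSY1 (log2 change -1.44), GSY2 (-0.63), GPH1 (-0.58), GLG1 (-1.66) and PGM2 (-0.42), all of glycogen and glucose phosphate metabolism, and SOL4 (-0.71). Besides HSP12 and XBP1, DDR2 rose 10.9-fold and YGP1 5.97-fold. Of 24 heat shock protein and chaperone genes 14 rose and 1 fell, led by HSP26 at 9.91-fold, HSP82 at 2.1-fold, HSP104 at 1.72-fold and HSP78 at 1.71-fold. Camera adjusted p was 0.00121 for general stress and 0.000487 for heat shock. With an estimated correlation the adjusted p was 0.515 and 0.26, respectively. Of 33 proteasome genes 18 rose and 1 fell, with the transcriptional activator gene RPN4 at 1.86-fold and RPN2 at 1.56-fold (camera adjusted p = 0.0215, adjusted p = 0.351 with an estimated correlation). That call was lost after centring each array on its median (adjusted p = 0.064) and without PFA replicate 1 (adjusted p = 0.0502), and ranged from 0.00498 to 0.351 over the 16 camera alternatives. Counts adjusted over the list alone were the same for general stress and heat shock and 17 higher for the proteasome.

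Glucose-repressed genes shifted up, with 10 of 17 higher, 1 lower and a median log2 change of 0.84. ADR1, encoding an activator of such genes, rose 9.37-fold, the malate dehydrogenase gene MDH2 3.68-fold and the succinate-fumarate transporter gene SFC1 at least 3.93-fold, the last with a mean DMSO signal below background. Of 22 genes under nitrogen catabolite repression, which serve the use of poor nitrogen sources, 18 rose and 2 fell. The arginine catabolism genes CAR2 and CAR1 rose 8.51-fold and 5.72-fold and the ammonium permease gene MEP1 5.92-fold. Genes of vacuolar proteases and autophagy rose in 14 of 15 cases, including the protease gene PRB1 at 5.33-fold, the carboxypeptidase gene CPS1 at 4.23-fold, the autophagy kinase gene ATG1 at 2.86-fold and the aminopeptidase gene APE1 at 2.52-fold. Camera adjusted p was 0.000587 for the glucose-repressed genes, 5.95e-05 for the nitrogen genes and 1.53e-06 for the vacuolar genes. With an estimated correlation, the adjusted p was 0.189 for the first and second of these lists and 0.171 for the third. Counts adjusted over the list alone were the same for these 3 lists.

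The phosphate regulon had 10 of 14 genes higher and 2 lower, with PHM8 at 12.3-fold, GIT1 at 2.33-fold, SPL2 at 2.27-fold and PHM6 at 2.1-fold. The high-affinity phosphate transporter gene PHO84 rose 1.19-fold. Of 17 genes of pleiotropic drug resistance, the network of efflux pumps and lipid-modifying proteins, 10 rose and 1 fell. RSB1 rose 6.17-fold, ICT1 4.71-fold, PDR10 3.53-fold and GRE2 3.08-fold, and the main efflux pump gene PDR5 rose 1.32-fold (log2 0.40 ± 0.06, SE). Camera adjusted p was 0.00243 for the phosphate and 0.00118 for the drug resistance list. With an estimated correlation the adjusted p was 0.275 and 0.26. Adjusted over the list alone, 10 phosphate and 11 drug resistance genes rose.

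The mating and pheromone response genes shifted down, with 15 of 16 lower, 1 higher and a median log2 change of -1.99. FAR1, which arrests division during mating, was 7.64-fold lower, PRM3 8.02-fold lower and FIG1 12.1-fold lower, the last with 1 of 3 PFA arrays below background. PRM6 was at least 18.0-fold lower and PRM2 at least 6.31-fold lower, both with a mean PFA signal below background. PRM4, the single member that rose, was 3.87-fold higher. All 4 alpha-cell markers fell. The alpha-agglutinin gene SAG1 was 17.3-fold lower, from 12079 ± 941 to 701 ± 110.4 (SD, n = 3), the a-factor receptor gene STE3 3.03-fold lower and MF(ALPHA)1, the main alpha-factor gene, 1.37-fold lower. Of 6 a-cell markers 4 fell, 1 rose and 1 did not pass the test. MFA1 was 8.7-fold lower, STE2 4.75-fold lower, MFA2 1.63-fold lower and AGA2 at least 7.63-fold lower, with a mean PFA signal below background for AGA2, whereas STE6 rose 1.44-fold. BAR1 had a log2 change of -0.61 (adjusted p = 0.0591). The a-cell markers were already dim in DMSO, where yeast probe sets had medians of 1018 to 1025 per array. Even so, all 6 lay above the background level on each DMSO array. Mean DMSO signals were 597 for MFA1, 476 for STE2, 159 for MFA2 and 155 for AGA2. On single DMSO arrays STE6 was at 91 to 113 and BAR1 at 66 to 82. Camera adjusted p was 2.02e-07 for the mating genes and 0.03 for the a-cell markers, and with an estimated correlation the adjusted p was 0.189 and 0.328. The a-cell call was lost after centring (adjusted p = 0.0548) and without DMSO replicate 1 (adjusted p = 0.0502), and its adjusted p ranged from 0.0112 to 0.328 over 15 camera alternatives. The alpha-cell markers were too few for camera. Adjusted over the list alone, 15 mating, 4 alpha-cell and 5 a-cell genes fell.

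**Figure D3:**
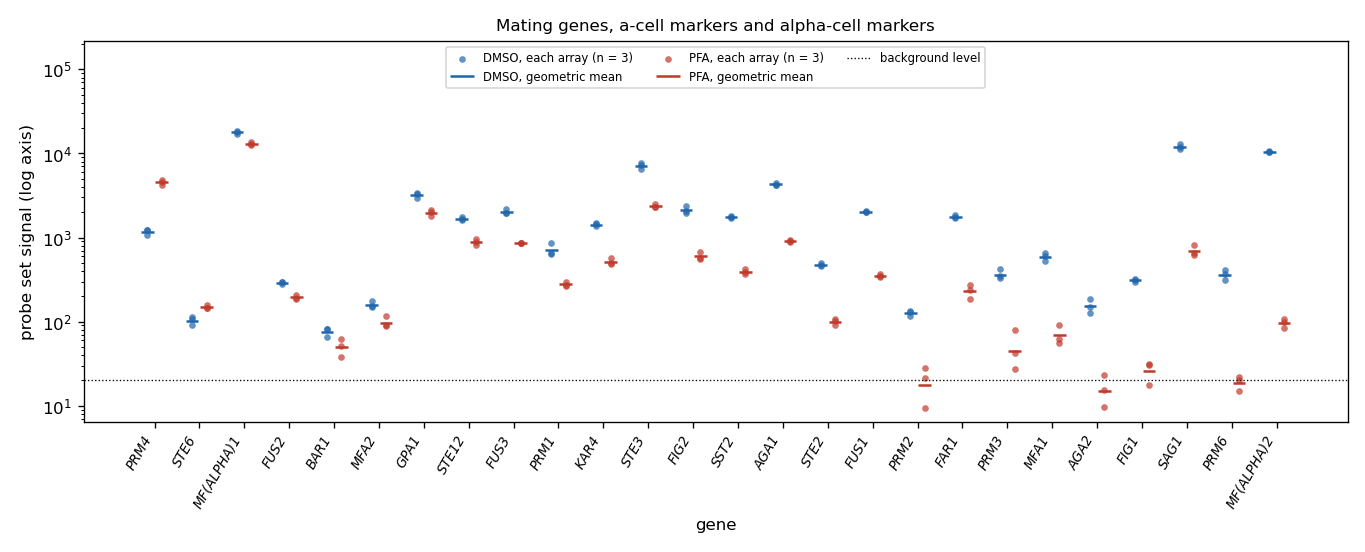
Probe set signal (log axis) of 26 mating genes and cell-type markers on each of the 3 DMSO (blue) and 3 PFA (red) arrays, with bars for the geometric means and a dotted line at the background level of 20.01. PRM4 and STE6 on the left lie higher in PFA, while MF(ALPHA)2 on the right drops 109-fold.

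Cell division genes fell in each phase examined. All 7 measured core histone genes were lower, with HTB2 at 4.75-fold and HHF1 at 2.18-fold lower. HHF1 was read on a probe set shared between sequences, so its value can mix near-identical copies. Of 15 G1/S genes 13 fell and 2 rose, including the B-type cyclin gene CLB6 at 6.74-fold, the cohesin gene MCD1 at 2.32-fold and the replication clamp gene POL30 at 2.24-fold lower. Of 8 G2/M genes 7 fell, with the mitotic cyclin genes CLB1 and CLB2 2.2-fold and 2.18-fold lower. All 11 daughter-cell and M/G1 genes fell, with PCL9 2.34-fold and AMN1 2.06-fold lower. Camera adjusted p was 0.000125 for histones, 0.000177 for G1/S, 0.000763 for G2/M and 0.000487 for M/G1. With an estimated correlation the adjusted p was 0.299, 0.171, 0.299 and 0.297. Counts adjusted over the list alone were the same.

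The list of ribosomal protein genes, drawn up by name, fell by a small amount in nearly every case, with 124 of 128 lower, none higher and a median log2 change of -0.30. The name pattern had also taken RPP1 (YHR062C), which encodes a subunit of RNase P, and without it 123 of 127 were lower (median -0.30, camera adjusted p = 3.96e-18, adjusted p = 0.189 with an estimated correlation). The 4 largest falls were in RPS28B (2.16-fold), RPL41A (2.07-fold), RPL22B (1.9-fold) and RPL4B (1.89-fold), and RPL41A alone of these had overlapping groups. Lists of other genes matched on signal had medians from -0.21 to -0.13 (central 95%), and hybridization controls a median of -0.091. Many ribosomal protein genes have near-identical copies, and 24 were read on probe sets shared between sequences. Of 85 ribosome biogenesis genes 50 fell and 3 rose, including MRT4 at 2.33-fold, MAK16 at 2.09-fold and NIP7 at 1.95-fold lower. Camera adjusted p was 3.84e-18 for ribosomal proteins and 1.4e-06 for ribosome biogenesis, and with an estimated correlation the adjusted p was 0.189 and 0.301. Adjusted over the list alone, 126 (125 without RPP1) and 50 fell.

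Sulfur and methionine genes were lower in 19 of 24 cases and higher in 1, with the S-methylmethionine permease gene MMP1 3.42-fold, MHT1 3.01-fold, MET1 2.51-fold and the S-adenosylmethionine permease gene SAM3 2.34-fold lower (camera adjusted p = 4.85e-06, adjusted p = 0.171 with an estimated correlation). Of 16 hypoxic and anaerobic genes 11 fell and 1 rose, with the heme synthesis gene HEM13 3.13-fold, AAC3 3.09-fold and TIR1 2.28-fold lower (camera adjusted p = 0.00493, adjusted p = 0.275 with an estimated correlation). Of 12 zinc regulon genes 8 fell and 3 rose, with the zinc transporter genes ZRT2 and ZRT1 5.62-fold and 3.14-fold lower (camera adjusted p = 0.0438, adjusted p = 0.324 with an estimated correlation). The zinc call was lost after centring (adjusted p = 0.0661), in limma without the variance trend (0.0667), without DMSO replicate 1 (0.0502) and without PFA replicate 1 (0.058), and ranged from 0.0132 to 0.324 over 16 camera alternatives. Counts adjusted over the list alone were the same for these 3 lists.

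**Figure D4:**
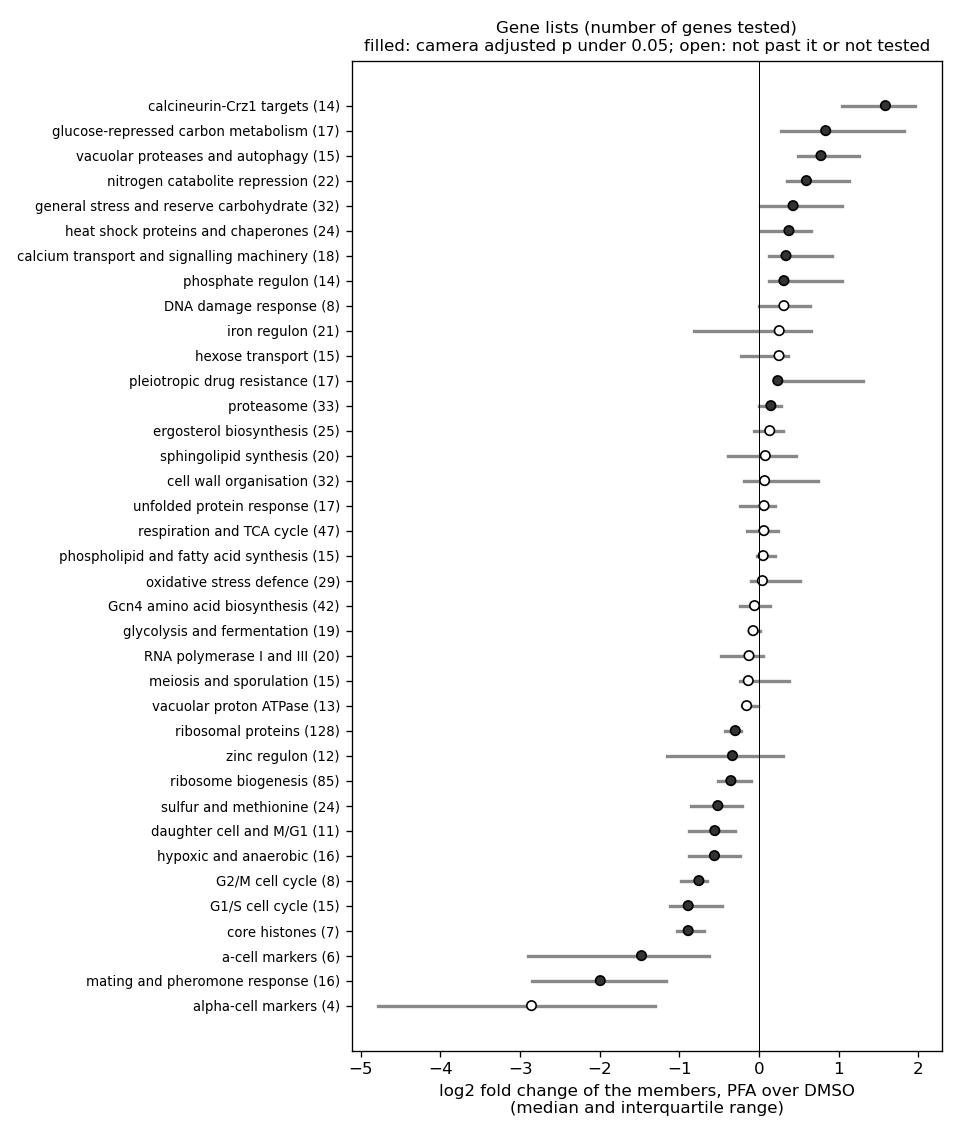
Median (points) and interquartile range (lines) of the log2 fold changes, PFA over DMSO, of the members of each of the 37 gene lists, with the number of genes tested in brackets. Filled points mark the 21 lists with a camera adjusted p under 0.05, from a median of 1.59 for calcineurin-Crz1 targets to -1.99 for mating genes, and the alpha-cell markers at -2.86 were not tested.

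The other 15 lists tested did not pass the threshold as groups, although single members changed. Of 25 ergosterol genes, the pathway of the fungal membrane sterol, 11 rose and 3 fell. The regulator gene UPC2 rose 3.26-fold, ERG26 1.47-fold and ERG9 1.4-fold, ERG24 fell 1.38-fold, and ERG11, the azole target, had a log2 change of -0.03 ± 0.05 (SE, adjusted p = 0.543; list adjusted p = 0.171). In cell wall organisation 15 of 32 rose and 9 fell, with YPS3 11.8-fold higher (list adjusted p = 0.104), and 5 listed genes are also Crz1 targets. Oxidative stress defence had 11 of 29 higher and 4 lower, with GTT2 2.75-fold higher and ATR1 2.67-fold lower (list adjusted p = 0.205). In phospholipid and fatty acid synthesis 5 of 15 rose and 1 fell, led by the inositol synthesis gene INO1 at 7.91-fold and the desaturase gene OLE1 at 1.81-fold (list adjusted p = 0.178). After quantile normalization these 4 lists passed the threshold, with adjusted p = 0.0351 for ergosterol and oxidative stress, 0.00862 for cell wall and 0.0188 for phospholipids, and the cell wall list also passed under the stricter filter on low values (adjusted p = 0.038). Over 16 camera alternatives the adjusted p ran from 0.0351 to 0.539 for ergosterol and oxidative stress, 0.00862 to 0.588 for cell wall and 0.0188 to 0.54 for phospholipids. Sphingolipid synthesis had 9 of 20 higher and 9 lower, with SUR1 2.47-fold and IPT1 2.46-fold higher and LAG1 1.66-fold lower (list adjusted p = 0.628).

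In the unfolded protein response 3 of 17 rose and 6 fell, with HAC1 1.46-fold higher and SEC61 1.46-fold lower. Its median log2 change was 0.06 and its mean -0.03 (list adjusted p = 0.995). The iron regulon had 12 of 21 higher and 8 lower, TIS11 2.15-fold higher and the ferric reductase gene FRE1 2.09-fold lower (list adjusted p = 0.505). Hexose transport had 7 of 15 higher and 2 lower, with MTH1 1.77-fold higher beside HXT5 (list adjusted p = 0.178). HXT17, below background on all 3 DMSO arrays and read on a probe set shared between sequences, was at least 2.43-fold higher. Glycolysis and fermentation had 4 of 19 higher and 6 lower, with PDC6 2.73-fold and PDC5 1.97-fold higher. Its median was -0.07 and its mean 0.08 (list adjusted p = 0.628), and after quantile normalization the median turned to 0.075 with an adjusted p of 0.0224, in a range of 0.0224 to 0.996 over 16 camera alternatives. Respiration and the TCA cycle had 13 of 47 higher and 7 lower, with LSC2 2.4-fold higher and the aconitase gene ACO1 2.11-fold lower (list adjusted p = 0.594).

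Of 42 Gcn4-dependent amino acid biosynthesis genes 9 rose and 15 fell, with ARG3 2.42-fold and SER33 1.83-fold lower (list adjusted p = 0.314). RNA polymerase I and III genes had 3 of 20 higher and 9 lower, with RRN3 1.79-fold higher and RPC31 1.62-fold lower (list adjusted p = 0.178). The vacuolar proton ATPase had 1 of 13 higher and 6 lower, with VMA7 1.33-fold lower (list adjusted p = 0.171). In the DNA damage response 4 of 8 rose and 1 fell, with DIN7 2.27-fold and RNR3 1.98-fold higher (list adjusted p = 0.136). Meiosis and sporulation genes had 4 of 15 higher and 2 lower, with DIT1 3.03-fold higher and SPO11 1.9-fold lower. Their median was -0.13 while camera's direction was up (list adjusted p = 0.844). Adjusted over the list alone, 10 sphingolipid genes rose, 10 polymerase and 14 Gcn4 genes fell, and 3 meiosis genes rose and 1 fell, with the other counts of these 15 lists the same. ACT1, the reference gene, had a log2 change of -0.03 ± 0.05 (SE, adjusted p = 0.562), and of 0.12 after quantile normalization (adjusted p = 0.0113, range 0.0113 to 0.937 over 15 alternatives).

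With 3 arrays against 3, an exact permutation of the labels cannot give a p below 0.1, so the limma p-values rest on the model's pooled spread. With a correlation estimated within each list, a form of camera that has 4 residual degrees of freedom here, 0 of 36 lists passed the adjusted threshold and 9 had an unadjusted p under 0.05.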

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

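The tests of a cells in the DMSO cultures, on a-cell and on alpha-cell markers, the addition of HO to the genes repressed in a/alpha cells and the comparison of ribosomal protein genes with the hybridization controls were chosen after the results were seen. Signal appeared in data outside the gene comparison: of 3517 unnamed probe sets, 424 were above background, and 73 of these were higher in PFA than in DMSO and 49 lower by limma at an adjusted p under 0.05. In 8 the rise was at least 4-fold, the largest from 223 ± 7.11 to 4320 ± 366 (SD, n = 3), 19.3-fold higher (adjusted p = 3.73e-13). Of 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave 3323 changed genes by limma and the highest of the others gave 0, or 96 at an unadjusted p under 0.05. These splits are too few for a share under 0.05. All but the real one also mix PFA and DMSO arrays in both groups. The difference between treatments then adds to the spread, so few calls are built in.

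Mating genes and cell-type markers of both mating types fell, and a bias that depends on signal is argued against, since 0% of 10000 lists of like signal had a median as low as the mating list's -1.99. A change to a/alpha cells in the PFA cultures would lower the genes repressed in such cells. But 7 of them outside the lists had a median log2 change of 0.087. Its bootstrap interval over genes, -0.55 to 0.28, lay above the bound of -1 set beforehand. For these 7 genes that argues against such a change as the whole cause. Genes in the mating list, 15 of 16 of which fell, were left out of the 7 beforehand, so the result does not cover them. With HO added to the 7, the median was 0.086 and the interval, -1.03 to 0.28, crossed the bound. The rule thus gave no verdict for the 8 genes. Of these 8, HO was 15.1-fold lower, STE4 2.04-fold lower (adjusted p = 7.07e-08) and STE18 1.46-fold lower, whereas STE5, AXL1 and RDH54 rose, and NEJ1 and RME1 did not pass the test. RNA of a cells mixed into the DMSO cultures would dilute the alpha-cell markers there. All 4 fell in PFA (median log2 change -2.86), so such dilution is argued against as the cause of their fall. This reasoning uses the pattern itself and does not bear on whether a cells were present in the DMSO cultures. For the a-cell markers, RNA of such cells stays open as a cause. Of the 6, 3 fell over 4-fold while MFA2 (log2 change -0.70) and BAR1 (-0.61) changed less. STE6, the only one with a 95% interval wholly above -1, rose by 0.52. Neither pheromone sent by such cells nor a response of the pheromone pathway to PFA was tested.

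The rise of calcineurin-Crz1 targets stood apart from a bias that depends on signal. A median of 1.59 exceeded that of 100% of 10000 lists matched on signal (central 95% from -0.32 to 0.26). After quantile normalization the median of the targets was 1.55. The arrays had a common trimmed mean before that step, and the median log2 change of all genes was -0.02. That step could therefore hardly have removed the rise, and no conclusion on scaling is drawn from it. No biological explanation was tested for the rise, and no calcium level was analysed here.

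The fall of ribosomal protein genes was small and shared in part by other bright genes. Lists matched on signal had medians between -0.21 and -0.13 in the central 95%, and 0% had a median as low as -0.30, which argues against signal-dependent bias as the whole cause. The hybridization controls, spike-ins of the standard protocol, had a median log2 change of -0.091 (bootstrap interval -0.17 to -0.04), which crosses the bound of -0.15 set beforehand and leaves array scaling open as a part. The ribosomal protein median lay 0.21 below that of the controls (difference -0.21, bootstrap interval -0.27 to -0.15). A single factor per array would move both sets alike, so it is argued against as the whole cause. These intervals are over genes or control probe sets and do not measure the spread between arrays. Slower growth in PFA at its IC50 was not tested and cannot be separated from a direct response in this design.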

How the results depend on the processing

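The alternatives with specific probe sets and without RPP1, which gave 21 lists again, were chosen after the data were seen. No list or named gene that was called reversed its direction. The excess of genes higher by at least 1.5-fold (715 against 556 lower) turned to an excess of lower genes after centring (613 against 713) and quantile normalization (633 against 646). The glycolysis median, not called, changed sign after quantile normalization. Among named genes 2355 values kept their side of the threshold, 12 lost it and 2 gained it, and among lists 563 kept it, 29 lost it and 16 gained it. The losses among named genes were in EKI1 and SPS1, and CNB1 (centred, log2 -0.19) and ACT1 (quantile normalization, log2 0.12) gained a call. A stricter filter on low values, which tested 2724 genes, gave 1893 changed, 813 higher, 1080 lower, and at least 1.5-fold 626, 342 higher and 284 lower, fewer because fewer genes were tested. Camera with an estimated correlation called 0 lists against 21 (9 at an unadjusted p under 0.05), with 4 residual degrees of freedom, while fry called 31 and quantile normalization 26. Leaving out single arrays gave 2962 to 3265 changed genes and 19 to 21 lists. The share of calls that were higher was 41.7% to 49.6% over the alternatives, against 48.8%. The replicate block gave 3366 changed genes, 3272 of them among the 3323. Same-numbered arrays had correlations of deviations of -0.05, -0.09 and 0.16, and replicate 3 of DMSO alone correlated best with its own number. So few pairs can neither show nor exclude a batch shared by same-numbered arrays. Signals near the background level of 20.01 limit the folds of SPS100, HXT17, SFC1, PRM6, PRM2, FIG1 and AGA2.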

Other observations

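The test of name families and the choice of amino acid uptake genes followed the sight of the results. Uptake genes for amino acids and peptides were not alike. BAP2 rose 22.1-fold, PTR2 25.5-fold and BAP3 4.33-fold, and TAT2 1.58-fold, AGP1 1.44-fold and DIP5 1.27-fold rose less, while GNP1 had a log2 change of 0.06 (adjusted p = 0.52) and TAT1 of 0.02 (adjusted p = 0.911). Of 227 families of genes that share the first letters of their names, 11 passed camera at an adjusted p under 0.05, and 0 with an estimated correlation (adjusted p = 0.849 for each of the 11). Among them 24 of 34 ATG (autophagy) genes rose and 1 fell (adjusted p = 0.000105), and 9 of 10 ADE (purine synthesis) genes fell (adjusted p = 0.000178, median log2 change -0.94). Of 9 COS genes, a subtelomeric family with similar sequences, 8 rose and 1 fell (adjusted p = 0.0137), and 10 of 12 ALG genes of protein glycosylation fell (adjusted p = 0.0141). By chromosome, the median log2 change ran from -0.06 on IX to 0.07 on VI.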
